A study of Homo sapiens with 6 samples.

How the data were processed

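Gene expression of LNCaP cells, an established human prostate cancer line, was measured on 6 arrays. Per the labels' protocols, cells were transfected with 7 µg of an empty FLAG expression plasmid or the same plasmid carrying BAF57, plus 1 µg of a plasmid for a fluorescent histone, kept for 24 h in medium with 5% charcoal-treated serum, and treated for 12 h with 0.1% ethanol or 1 nM DHT. RNA was extracted with Trizol and a Qiagen column and labelled with biotin by the NuGEN protocol, per the labels' protocols. The authors deposited 1 intensity value per probe set and array on a linear scale, made with Affymetrix Expression Console 1.1 per the submitters' processing notes. The background correction, the summarisation of probes and the normalization between arrays are not given in the sources used here. The deposited intensities ran from about 0.00012 to 7143 and their medians over all probe sets were 28.0 and 31.9 on the vector vehicle arrays (replicates 1 and 3), 30.5 and 27.5 on the BAF57 arrays (2 and 3) and 27.3 and 29.99 on the DHT arrays (2 and 3). These medians lie close together without being equal, so some scaling by the authors is possible and its kind stays unknown.

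Groups and replicate numbers came from the sample titles. Per the design text the arrays of a group are biological duplicates, and p-values measure the spread between them. Nothing gave a batch, and 0 columns of other samples were in the table. The number of arrays, 2 per group, limits the precision.

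Of the 33297 probe sets, 19460 had exactly 1 gene symbol in the platform annotation, 1754 had several and 12083 were not listed there. The 19460 covered 18417 genes, and 19429 of them had their Entrez identifier in a RefSeq gene table of assembly GRCh38.p14, used for names only, with 0 symbols updated. No coordinates were used. TMPRSS2 and FKBP5 lay only on probe sets with several symbols, a kind that was fitted separately and not named, so no value is given under these names. Intensities were taken to log2 after adding a pseudocount of 1, so fold changes are on the log2(intensity + 1) scale, which understates the change of dim genes. Each gene was represented by its probe set with the highest mean, and genes with a mean below the 30th percentile (a level of 4.46) were left out, which removed 5525 genes and kept 12892.

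All 6 arrays were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3, which left 3 residual degrees of freedom and gave 6.62 prior ones. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. The comparisons were BAF57 against vector in vehicle, DHT against vehicle in vector cells, and BAF57 in vehicle against DHT in vector. The 32 gene lists were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists of a comparison, and members were also adjusted over the list alone. With an estimated correlation camera had little power on so few arrays. The fibroblast list, with an estimate of 0.0038, had a camera p of 0.0158 for BAF57 with the preset and 0.0918 with the estimate. Not passing with an estimated correlation therefore does not show that correlation accounts for a list. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. The lists of basal, endothelial, fibroblast, blood cell and neuroendocrine markers stood for other cells a culture could hold. Since the BAF57 and DHT effects share the vector arrays, 100 simulations of unchanged groups against those arrays gave the values without any effect. For the overlap, a further 100 took as many top genes of a simulated group as were called with DHT, a check chosen after the overlap was seen.

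The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made afterwards. The rule took SMARCE1, ITGA2 and KLK3 in each comparison, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, up to 4 called members of each list or else 2 uncalled ones, and, where under 5 genes passed, the 10 with the largest moderated t in each direction. It also took TMPRSS2 and FKBP5, 1 further gene that is not reported here, and the 8 largest of the genes called in both the BAF57 and the DHT comparison, of which there were 0. ITGA2 had been chosen from knowledge of the study.

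The alternatives were centring or quantile normalization of the arrays, no level filter or one at the 50th percentile, the mean of a gene's probe sets, eBayes with trend and robust settings, a pseudocount of 16, only the 4 arrays compared, the replicate number as a block, each array left out in turn, and an unadjusted p under 0.05 with a change of 1.5-fold. Array weights and a crossed pairing were added after the data were seen. With 1 array left out its group keeps a lone array, so p-values and calls of that fit hold no spread within that group. Probe sets with several or no symbols were fitted separately and not named.

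The fit was tested on simulated data with 200 of 12892 genes changed in the BAF57 comparison. Of genes changed by 1 log2 unit it called 12%, by 2 units 86%, and by 3 or 4 units 100%. Of the 163 genes called 14 were unchanged, and estimates followed the planted changes with a slope of 0.984. In the DHT comparison of these data, where nothing was planted, 0 genes were called. In a separate simulation of the DHT comparison a list of 30 genes planted with a change of 0.7 log2 units was found, and 0 of 31 random lists passed. Both simulations drew genes independently of each other. The random lists therefore say nothing about false passes of lists whose genes move together, and the estimated correlation of the mitosis list was 0.850. In the closing tests, 3 earlier tests were replaced after their outcome was seen, because they ran on genes chosen by their call or on part of the genes concerned. The comparison of replicates over the DHT-risen genes still uses genes chosen by their call, as the pattern consists of them.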

Results

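By its title and design text, the study concerned the transcripts that change when prostate cancer cells carry extra BAF57, a subunit of the SWI/SNF chromatin remodelling complex encoded by SMARCE1, with a response to an androgen beside it. Gene expression was measured on 6 one-colour oligonucleotide arrays of LNCaP, an established human prostate cancer line that expresses the androgen receptor. There were 3 groups with 2 arrays each. Cells with the empty vector and vehicle (replicates 1 and 3), cells with the BAF57 plasmid and vehicle (replicates 2 and 3), and cells with the empty vector and 1 nM dihydrotestosterone, DHT (replicates 2 and 3), were collected after 12 h. The design text calls the arrays of a group biological duplicates. No array with both BAF57 and DHT was analysed here. Values are log2(intensity + 1), and 12892 genes were tested. The median deposited intensity over all 33297 probe sets lay between 27.3 and 31.9 on the 6 arrays. The number of arrays limits the precision.

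The pairs of arrays differed in how closely they matched. The 2 BAF57 arrays correlated at r = 0.954 across genes and the 2 DHT arrays at r = 0.963, and 3.96% and 2.61% of genes lay more than 2-fold apart within these pairs. The 2 vector vehicle arrays correlated at r = 0.870, with 17.3% of genes more than 2-fold apart. Vector vehicle replicate 1, the only array that carries that number, had 31 genes more than 2 log2 units above all 5 other arrays and 227 genes as far below them. On each of the other arrays these counts were 0 or 1. CBLN2, a cerebellin precursor, measured 9.56 on this array and at most 3.64 elsewhere, and LPL, lipoprotein lipase, measured 0.17 there and at least 6.75 elsewhere. Genes are not independent replicates, so these correlations describe the arrays.

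**Figure D1:**
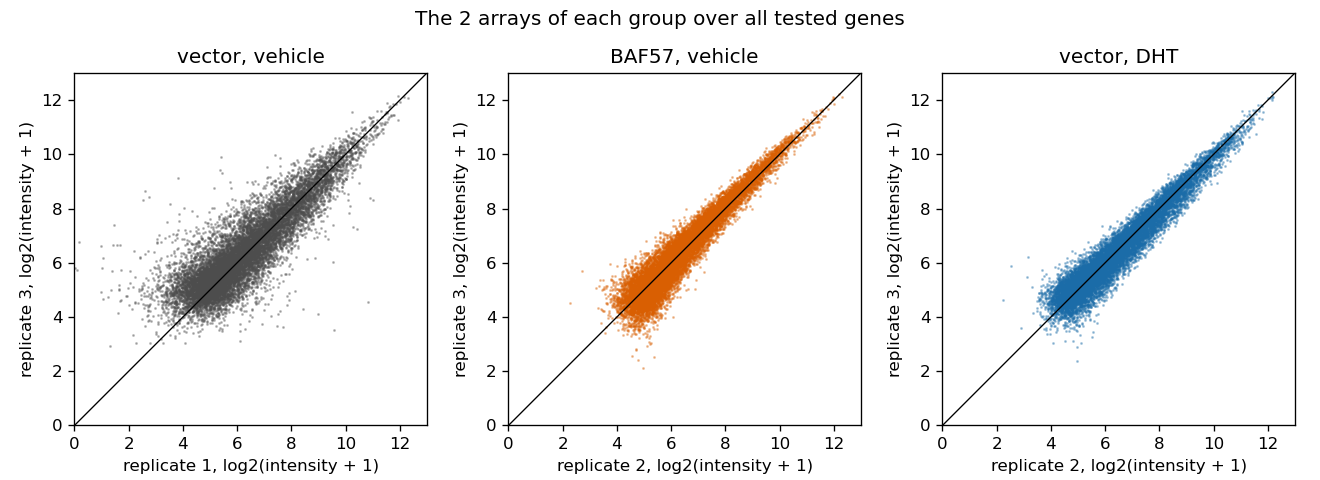
Each point is 1 of the 12892 tested genes, with its level on the first array of a group on the x axis and on the second array on the y axis, both as log2(intensity + 1), and the line marks equal levels. The vector vehicle pair spreads most widely, with 17.3% of genes more than 2-fold apart, against 3.96% in the BAF57 pair and 2.61% in the DHT pair.

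SMARCE1, the gene carried by the plasmid, measured 8.20 and 8.28 on the vector vehicle arrays and 9.39 and 9.42 on the BAF57 arrays, a log2 difference of 1.16 ± 0.29 (SE, n = 2 per group), or 2.24-fold. Both BAF57 arrays lay above the other 4. The difference did not pass the test across genes (limma, Benjamini-Hochberg adjusted p = 0.313). ITGA2, the integrin alpha 2 subunit of a collagen receptor, measured 3.27 and 5.48 with vector and 6.19 and 6.58 with BAF57, and its log2 difference of 2.0 ± 0.59 did not pass (limma adjusted p = 0.313). With vector vehicle replicate 1 left out, the ITGA2 difference was 0.90 and that of SMARCE1 1.12. With replicate 3 left out instead, the differences were 3.11 for ITGA2 and 1.20 for SMARCE1. Each of these fits has 1 vector array and takes its spread from the BAF57 and DHT pairs alone. KLK3, the gene of prostate-specific antigen, measured 7.32 and 6.51 with vector and 6.38 and 6.32 with BAF57, a log2 difference of -0.57 ± 0.36 that did not pass (limma adjusted p = 0.450) and was -0.16 without vector vehicle replicate 1 and -0.97 without replicate 3. Where the probes lie within the SMARCE1 transcript was not analysed here.

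**Figure D2:**
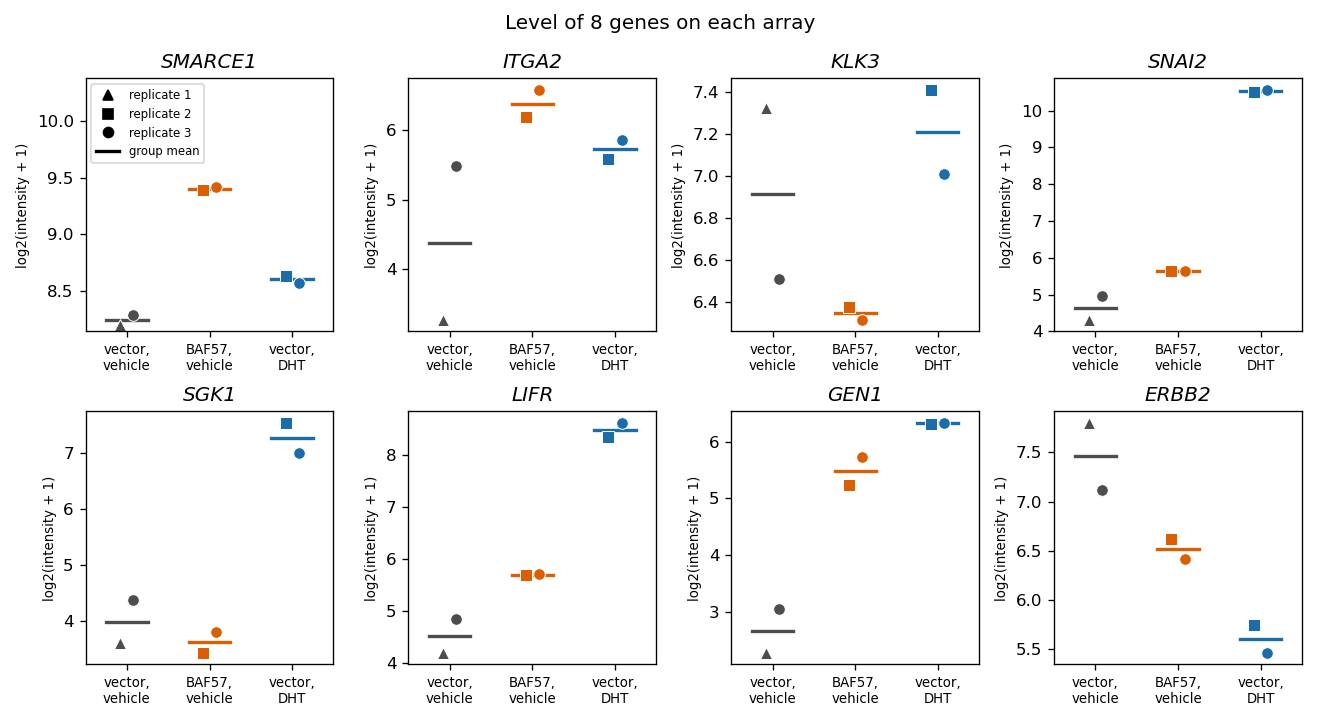
Levels of 8 genes as log2(intensity + 1) on the y axis of each panel, whose range differs between panels and does not start at 0, with the 3 groups on the x axis, a symbol per array shaped by its replicate number and a bar at the group mean. SMARCE1 reached 9.39 and 9.42 with BAF57 against 8.20 to 8.63 on the other arrays, and SNAI2 reached 10.50 and 10.56 with DHT.

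No gene passed the adjusted threshold between BAF57 and vector cells, so the following values are the largest by moderated t and did not pass. GEN1, a Holliday junction resolvase, was 7.08-fold higher with BAF57 (log2 2.82 ± 0.36, limma adjusted p = 0.224, the lowest of all genes). TTK, a kinase of the spindle checkpoint, had a log2 difference of 3.21 ± 0.52, and MNS1, a nuclear structural protein of meiosis, one of 2.70 ± 0.49. On both vector arrays GEN1 and TTK lay below the filter level of 4.46, so their differences start from dim values. RAD17, which loads a checkpoint clamp at damaged DNA, differed by 1.98 ± 0.36, the membrane scaffold gene DLG2 by 1.78 ± 0.32, and AP4E1, an adaptor complex subunit, by 2.36 ± 0.42. The zinc finger genes ZNF761 and ZNF675 differed by 2.09 and 1.92, VPS50 of endosomal recycling by 1.84 and CYB5R4 by 1.90. In the other direction, log2 differences were -1.68 for CBLN3, -1.66 for the small nucleolar RNA gene SNORD38A, -1.62 for the transcriptional repressor HES7, -1.60 for the glutamate receptor GRM4, -1.43 for METTL27, -1.42 for MAGEE1, -1.36 for ANKRD24, -1.34 for CMTM8, -1.29 for FAM218A and -1.26 for WDR90. The SNORD38A difference was -1.10 without vector vehicle replicate 1.

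Among the 32 gene lists, genes of G2 and mitosis stood highest with BAF57. None of the 37 measured members passed over all genes, 36 were higher, the median log2 difference was 1.13, and 13 were called when adjusted over the list alone, TTK and NUF2 (2.45) among them. The list passed limma's camera with a preset correlation (camera adjusted p = 4.93e-10) and not with an estimated correlation (adjusted p = 0.861). DNA replication genes (median 0.50 over 38 genes, camera adjusted p = 0.00480) and secretory and glycosylation genes (median 0.62 over 22 genes, adjusted p = 0.00620) lay higher than other genes in the preset test, and cytosolic ribosomal protein genes lower (median -0.27 over 41 genes, adjusted p = 0.00480). Each of these 3 lists had a camera adjusted p of 0.861 with an estimated correlation. That form had little power with so few arrays, so not passing it does not show that correlation accounts for a list. The other 28 lists had preset adjusted p of 0.0845 or more, and no list had a called member over all genes. In the interferon list only IFIT5 was called over the list alone, with a log2 difference of 1.69. The list of genes raised by androgen had a median of 0.08 over 60 genes (camera adjusted p = 0.473), and integrin subunits a median of 0.07 over 14 genes (adjusted p = 0.984). Vector vehicle replicate 1 moved with these groups. Without it the mitosis median was 0.23, the replication median 0.14, the secretory median 0.28 and the ribosomal median -0.08, and the replication, secretory and ribosomal lists no longer passed the preset test (camera adjusted p = 0.668, 0.176 and 0.668). NUF2 then differed by 1.40 (limma adjusted p = 0.309). The mitosis list still passed (camera adjusted p = 0.000435), and interferon genes (median 0.14, adjusted p = 0.000468) and histone genes (median -0.40, adjusted p = 0.000962) then passed too, each with an adjusted p of 0.987 with an estimated correlation.

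The comparison of BAF57 with vector called 0 of 12892 genes (limma, adjusted p under 0.05), while 1880 genes had an unadjusted p under 0.05, 1447 of them higher and 433 lower with BAF57, where 644.6 would be expected by chance. This excess depended on single arrays. Without BAF57 replicate 3, a fit with 1 BAF57 array, fewer genes than expected by chance reached that level. The 2 arrays of one group lay wholly apart from those of the other for 48.9% of genes, and chance gives 33.3%. Without vector vehicle replicate 1 the log2 differences were 2.44 for GEN1, 2.41 for TTK and 2.47 for the phospholipase gene PNPLA8. PNPLA8 lay outside the rule for named genes and was singled out after its values were seen. Fits without either vector vehicle array hold no spread between vector arrays, so their calls rest on the spread of the BAF57 and DHT pairs. Without vector vehicle replicate 3, 2045 genes were called higher and 657 lower.

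With DHT 811 genes rose and 84 fell in vector cells (n = 2 arrays per group), and SNAI2, a zinc finger repressor known for its part in epithelial-mesenchymal transition, rose most. SNAI2 measured 4.31 and 4.97 with vehicle and 10.50 and 10.56 with DHT, a 59.4-fold rise (log2 5.89 ± 0.33, limma adjusted p = 0.000138). The next largest rises were DLG2 at 4.36 ± 0.32, TTK at 4.11 ± 0.52, the leukaemia inhibitory factor receptor gene LIFR at 3.96 ± 0.33 and the small GTPase gene RHOU at 3.89 ± 0.45 (limma adjusted p from 0.000799 to 0.0132). SPART, CRYBG1, the condensin gene NCAPG, GEN1, the scaffold gene IQGAP2, ZNF385B and MNS1 rose by 3.76, 3.76, 3.75, 3.67, 3.61, 3.59 and 3.49 on the log2 scale. When vector vehicle replicate 1 was left out, SPART rose by 1.94, CRYBG1 by 1.76, NCAPG by 1.85, IQGAP2 by 2.47 and ZNF385B by 2.30. With replicate 3 left out instead, CRYBG1 rose by 5.75 and NCAPG by 5.64.

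The largest falls with DHT were smaller. FAM177B fell by 2.56 ± 0.56 on the log2 scale, BAMBI, a pseudoreceptor that dampens TGF-beta signalling, fell by 2.45 ± 0.61, and the U1 small nuclear RNA gene RNVU1-19 fell by 2.23 ± 0.50. The epithelial transcription factor gene ELF3 fell by 2.20 ± 0.37, the pyruvate dehydrogenase kinase gene PDK2 fell by 1.90 ± 0.43 and ERBB2, the HER2 receptor gene, fell by 1.85 ± 0.34. The remaining 6 were ISG15 (-1.83), KRT71 (-1.82), SNORD38A (-1.78), the protease gene PRSS23 (-1.72), ACP3, which encodes prostatic acid phosphatase (-1.67), and SNORD116-6 (-1.67). Limma adjusted p-values for these 12 genes lay between 0.0204 and 0.0460. In the fit without vector vehicle replicate 1 the changes of BAMBI, RNVU1-19, ISG15 and ACP3 were -1.30, -1.48, -1.26 and -1.09, and ISG15 and ACP3 no longer passed (limma adjusted p = 0.0519 and 0.0764).

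Of the 60 measured genes known to be raised by androgen, 30 rose with DHT and none fell (median log2 change 1.25), and adjusted over the list alone 38 rose and 1 fell. Besides SNAI2 and RHOU, the kinase gene SGK1 rose by 3.28 ± 0.37 (limma adjusted p = 0.00974) and the transporter gene ABCC4 by 3.03 ± 0.42. The list passed camera with a preset correlation (adjusted p = 1.82e-14) and fry (adjusted p = 0.0139). It did not pass camera with an estimated correlation (adjusted p = 0.448), a form with little power here. KLK3 measured 7.41 and 7.01 with DHT, and its log2 change of 0.29 ± 0.36 did not pass (limma adjusted p = 0.632). It was 0.70 without vector vehicle replicate 1 and -0.11 without replicate 3. ITGA2 differed by 1.35 ± 0.59 and SMARCE1 by 0.36 ± 0.29, neither past the test (limma adjusted p = 0.174 and 0.458). The ITGA2 difference was 0.24 without vector vehicle replicate 1 and 2.45 without replicate 3. Of 16 genes known to be lowered by androgen, ACKR3, a chemokine receptor gene, fell by 1.55 ± 0.35 and PAK1IP1 rose by 2.82 ± 0.31, and 14 did not pass (2 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.112). Among 15 luminal prostate genes the cold-sensing channel gene TRPM8 rose (2.98) while GATA2 (-1.62) and ACP3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.962). Without vector vehicle replicate 1 the luminal median moved from 0.16 to 0.70, with 4 genes risen and 1 fallen (camera adjusted p = 0.0561), and among the androgen-lowered genes 3 rose and 1 fell (median -0.30 in place of -0.60, camera adjusted p = 0.834).

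Several genes of the cell cycle and of the secretory pathway rose with DHT. Of 37 mitosis genes 13 rose (23 adjusted over the list alone), among them TTK, NUF2 (3.32), HMMR (3.20) and TOP2A (2.93), with a camera adjusted p of 2.36e-09 and one of 0.880 with an estimated correlation. The mitosis median was 1.54, and 0.77 without vector vehicle replicate 1. Of 38 replication genes CCNE2 (2.10) and POLE2 (1.75) rose (4 over the list alone), and the list's camera adjusted p of 0.0147, against an adjusted p of 0.962 with an estimated correlation, became 0.579 without that array. Of 22 secretory and glycosylation genes 5 rose (12 over the list alone), led by the COPII coat gene SEC24D (2.71), the sialyltransferase gene ST6GALNAC1 (2.05) and UAP1 (1.86), which makes UDP-N-acetylglucosamine (camera adjusted p = 1.12e-05, and adjusted p = 0.880 with an estimated correlation). Of 24 unfolded protein response genes 6 rose, including the chaperone genes DNAJC3 (2.30) and DNAJB9 (2.06), and the list did not pass (camera adjusted p = 0.112). Without vector vehicle replicate 1, POLE2 and TRAM1, which was among the 5 secretory genes, no longer passed (limma adjusted p = 0.0683 and 0.0875), with POLE2 at 1.15, and HMMR, TOP2A, CCNE2 and DNAJC3 rose by 1.85, 1.64, 1.30 and 1.45. The unfolded protein list passed the preset test in that fit (camera adjusted p = 0.0493, and adjusted p = 0.934 with an estimated correlation).

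Replication-dependent histone genes lay lower with DHT, with a median of -0.68 over 40 genes, 3 of them higher and none called singly (camera adjusted p = 1.12e-05). Ribosomal protein genes (median -0.28 over 41, adjusted p = 0.00266) and respiratory chain genes (median -0.38 over 36, adjusted p = 0.0354) also lay lower with no member called. With an estimated correlation the camera adjusted p of these 3 lists lay between 0.880 and 0.962, and without vector vehicle replicate 1 the ribosomal and respiratory chain lists did not pass the preset test (camera adjusted p = 0.286 and 0.410, with medians of -0.15 and -0.18), while the histone list did (adjusted p = 2.09e-09) and 4 of its genes fell.

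Other lists held a few genes called with DHT and did not pass camera with a preset correlation (adjusted p from 0.0536 to 0.962). Of 18 TGF-beta and BMP genes 5 rose, including the receptor genes BMPR1B (3.32) and TGFBR1 (2.15) and the matrix gene THBS1 (3.12), and BAMBI fell. Of 32 adhesion and migration genes ROCK2 (2.31), ROCK1 (1.94), ENAH (1.62) and WASL (1.40), which act on actin, rose. Of 14 integrin subunits ITGAV rose (1.79) and ITGA3 fell (-1.46), and of 20 epithelial junction genes CLDN4 (-1.40) and ELF3 fell. Both SWI/SNF genes called out of 25 rose, ARID2 by 2.13 and PBRM1 by 1.94. The elongases ELOVL7 (2.79) and ELOVL5 (2.16) rose among 16 fatty acid genes, SC5D (1.67) and IDI1 (1.55) among 17 cholesterol genes, THBS1 and COL12A1 (2.37) among 30 matrix genes, and ADAM9 (1.49) and ADAM10 (1.18) among 25 protease genes. The Wnt receptor gene FZD5 rose (2.47) and RNF43, a ubiquitin ligase gene that limits Wnt receptors, fell (-1.39) among 14 Wnt genes, and IFIH1 rose (1.30) and ISG15 fell among 31 interferon genes. Single calls were NDRG1 (2.45) of 27 hypoxia and glycolysis genes, POLK (1.68) of 19 p53 targets, ATF5 (-1.33) of 27 amino acid response genes, IER2 (-1.43) of 19 immediate early genes and SNAI2 of 11 mesenchymal genes. No member was called among basal epithelial, endothelial, fibroblast, blood cell, neuroendocrine and inflammatory genes. Without vector vehicle replicate 1, ROCK1, ENAH, WASL, CLDN4, PBRM1, IDI1, ADAM10, IFIH1, ISG15, ATF5 and IER2 no longer passed (limma adjusted p from 0.0519 to 0.102). In that fit the rises of THBS1, TGFBR1, ROCK2 and ARID2 were 1.82, 1.34, 1.33 and 1.41, and PBRM1 and ENAH differed by 1.11 and 1.08. The amino acid response list, with a median of 0.20 over all arrays, had one of -0.48 there, with 3 members fallen and a camera adjusted p of 0.0459 (adjusted p = 0.934 with an estimated correlation). Among the interferon genes 4 rose and 0 fell there, and the list's median moved from -0.42 to -0.21 and its camera adjusted p from 0.0536 to 0.876. Adjusted over the list alone, 5 rose and 3 fell among TGF-beta and BMP genes, 4 and 1 among adhesion genes, 3 and 4 among integrins, 5 and 5 among junction genes, 5 and 2 among cholesterol genes, 2 and 1 among fatty acid and among Wnt genes, 3 and 3 among interferon genes, 1 and 1 among amino acid response genes and 1 and 0 among blood cell genes, and the other lists of this kind had their counts over all genes.

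**Figure D3:**
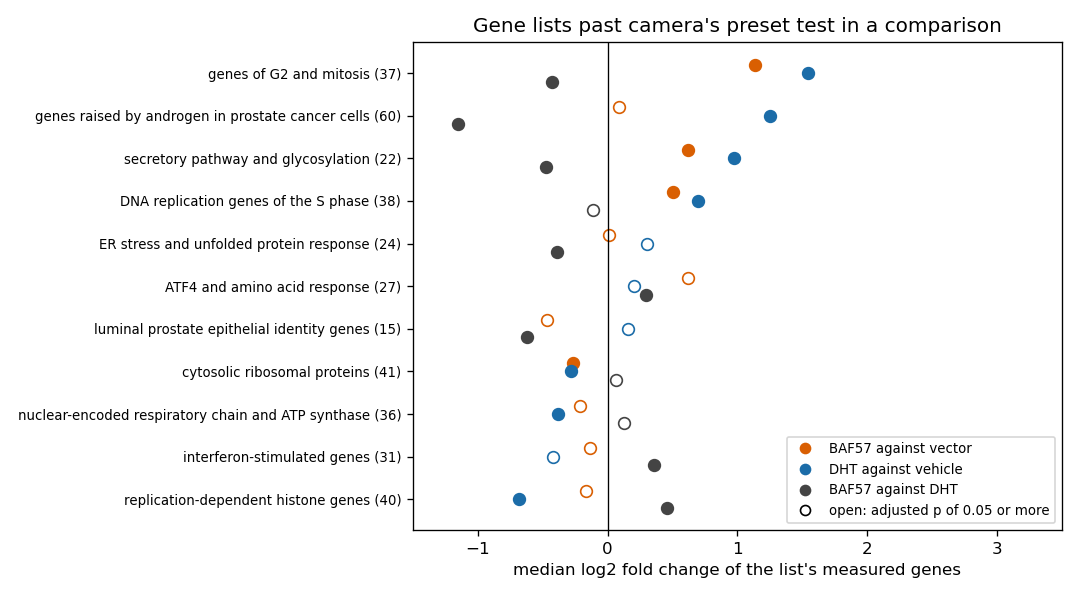
Median log2 fold change (x axis) of the measured genes of each of the 11 lists that passed limma's camera with a preset correlation in at least 1 comparison (y axis, number of genes in brackets), with 1 dot per comparison, filled where the adjusted p was under 0.05. Mitosis genes have the highest DHT median at 1.54 and androgen-raised genes the lowest median of BAF57 against DHT at -1.15, and no list passed with an estimated correlation.

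The DHT comparison called 895 of 12892 genes (limma, adjusted p under 0.05), 327 of the rises being more than 4-fold, and all 895 had both DHT arrays wholly above or below both vehicle arrays. The count was 2 without either BAF57 array, which adds only to the estimate of the spread, 1 without either DHT array, 801 without vector vehicle replicate 1 (670 rose and 131 fell, 625 of them shared), 3840 without vector vehicle replicate 3, 2 from the 4 arrays of these groups alone and 4 with no filter on low values, and SNAI2 passed in each (limma adjusted p from 9.25e-11 to 0.0152).

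BAF57 cells in vehicle and vector cells in DHT differed in 7 genes, each lower with BAF57, which tests whether a gene differed between these treatments. SNAI2 was 29.6-fold lower with BAF57 (log2 -4.89 ± 0.33, limma adjusted p = 0.000790). The others were RHOU (-3.80 ± 0.45), SGK1 (-3.65 ± 0.37), LIFR (-2.78 ± 0.33), NDRG1, a stress-responsive growth regulator (-2.67 ± 0.30), DLG2 (-2.58 ± 0.32) and PAK1IP1 (-2.47 ± 0.31), with limma adjusted p-values from 0.0172 to 0.0306. All 7 rose with DHT. Without any 1 BAF57 or DHT array none of them passed, and the limma adjusted p of SNAI2 lay between 0.0577 and 0.137. Log2 differences that did not pass were -2.63 for the prostate transporter gene SLC45A3, -2.18 for BMPR1B, -1.89 for SEC24D, 1.76 for RNF43, 1.63 for ELF3, 0.80 for SMARCE1, 0.66 for ITGA2 and -0.86 for KLK3.

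Androgen-raised genes as a list lay lower with BAF57 than with DHT, with a median of -1.15 over 60 genes, 4 called over all genes and 38 lower and 1 higher over the list alone. Camera with a preset correlation gave an adjusted p of 3.55e-36 and fry one of 0.0261, while camera gave an adjusted p of 0.121 with an estimated correlation. The mesenchymal list passed fry alone (adjusted p = 0.0461), SNAI2 being its called member. In the preset test secretory (-0.47), unfolded protein (-0.39), mitosis (-0.43) and luminal prostate genes (median -0.62) also lay lower with BAF57, and histone (0.45), interferon (0.36) and amino acid response genes (median 0.30) higher, with camera adjusted p from 1.54e-06 to 0.0153. None of their members was called over all genes, and adjusted over the list alone 2 luminal genes were higher and 5 lower and 1 secretory gene was lower. With an estimated correlation each of these 7 lists had a camera adjusted p of 0.696 or more. The comparison had 795 genes at an unadjusted p under 0.05 against 644.6 expected. Leaving out any 1 BAF57 or DHT array left 0 calls by limma with 346 to 670 genes at an unadjusted p under 0.05, and leaving out either vector vehicle array, which enters here only through the estimate of the spread, gave 34 genes higher and 127 lower with BAF57. In the fit without vector vehicle replicate 1 the genes called lower included 27 androgen-raised, 4 luminal, 2 secretory and 1 unfolded protein gene, and those called higher 1 histone and 1 amino acid response gene.

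Across all 12892 genes the BAF57 effect and the DHT effect correlated at r = 0.849 (Spearman's rho = 0.811), and 82.1% of genes had the same sign. Both effects were measured against the same vector arrays, and simulated unchanged groups that shared 1 simulated vector group gave r = 0.762 and 77.6%. Genes were drawn independently there, so the simulated ranges are likely too narrow. The covariance was 0.442 against 0.133 in the simulation, and the spread between the 2 vector arrays alone would add 0.171. The covariance was 0.968 without vector vehicle replicate 3 and 0.241 without replicate 1, fits with 1 shared vector array. That array alone would add 0.342 if both vector arrays varied alike. Replicate 1 stood much further from the other arrays than replicate 3 did, so replicate 3 may add less. Whether 0.241 holds an excess therefore cannot be told. Of the 811 genes that rose with DHT, 98.3% were higher with BAF57, with a median log2 difference of 1.15. Among the 811 genes that ranked highest in 1 unchanged simulated group, 98.4% were on average higher in the other. The observed share is thus no larger than a shared simulated vector group gives. Of the 811, 640 had an unadjusted p under 0.05 with BAF57, where unchanged groups shared 186 on average (163 to 213) and independent lists would share 91.0. More genes reached that level with BAF57, 1447 against 281.7, so the overlaps of 640 and 186 are not on an equal footing. The DHT-risen genes were 44.2% of the 1447, against 66.2% in unchanged groups. These shares cannot be compared, because 811 genes are too few to make up so large a share of 1447. Of the 84 genes that fell, 28 were lower with BAF57 at that level, where unchanged groups shared 48.6 on average and independent lists would share 2.82, and 0 genes went in opposite directions at that level, as in all 100 simulations of unchanged groups. At any p, 3.57% of the 84 were higher with BAF57, where unchanged groups gave at most 1.19%. With 2 vector arrays the controls could not be split with 2 arrays on each side, so part of the overlap may come from the shared controls. With 1 vector array for each effect the covariance was 0.312 or 0.249, by which array served which effect. GEN1 and TTK are examples. GEN1 measured 2.27 and 3.04 with vector, 5.24 and 5.72 with BAF57 and 6.32 and 6.33 with DHT. TTK measured 1.31 and 2.91 with vector, 4.80 and 5.84 with BAF57 and 6.19 and 6.24 with DHT. The vector levels of both lay below the filter level of 4.46, so these genes passed the filter on the mean through the other arrays.

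**Figure D4:**
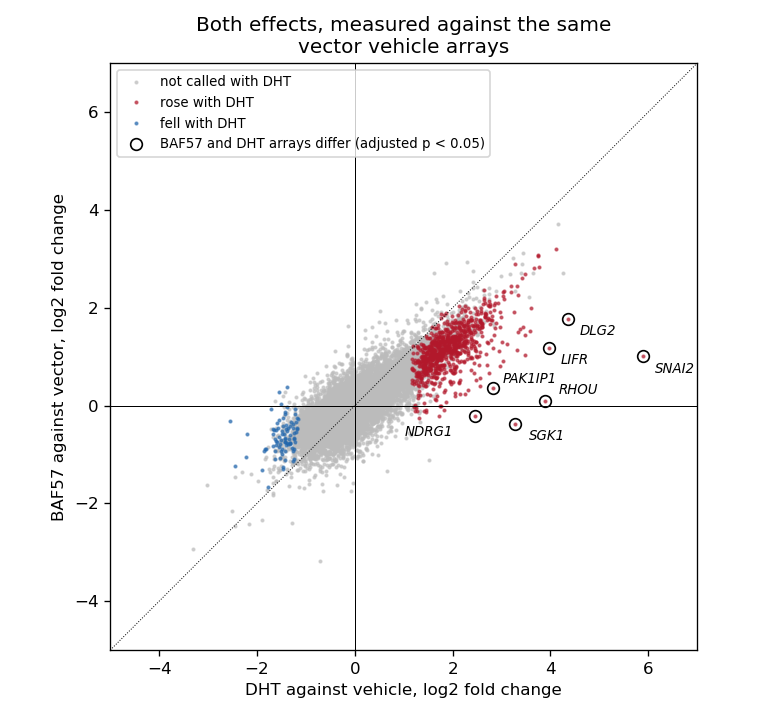
Each point is 1 of the 12892 tested genes, with the DHT effect on the x axis and the BAF57 effect on the y axis, both as log2 fold changes against the same vector vehicle arrays, coloured by the call with DHT, with circles around the 7 genes that differed between BAF57 and DHT arrays and a dotted line where both effects are equal. The points follow a rising band (r = 0.849, against 0.762 for simulated unchanged groups), and the circled genes lie below the line.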

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

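Probe sets with several gene symbols or none stood outside the comparisons, and their tests were chosen after the named genes had been tested. Probe set 8125919, which carries several gene symbols and therefore names no gene here, measured 10.21 and 10.10 on the DHT arrays against 5.85 and 7.22 on the vector vehicle arrays and 7.48 and 7.66 on the BAF57 arrays. Both DHT arrays lay more than 2 log2 units above the other 4. Its log2 difference with DHT was 3.62 ± 0.43 and did not pass among the 5903 probe sets of this kind (limma adjusted p = 0.0791). None of these probe sets passed with limma in any comparison, with 476 at an unadjusted p under 0.05 for BAF57 against vector, 1298 for DHT and 386 for BAF57 against DHT. No explanation was tested for it.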

How the results depend on the processing

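Array weights and the crossed pairing were chosen after the data were seen, and the other alternatives before. The 0 calls of BAF57 against vector held under each alternative with an adjusted p except leaving out a vector vehicle array, while the counts for DHT and for BAF57 against DHT moved with the filter, the spread estimate and the arrays. SMARCE1 and SNAI2 kept their direction under all alternatives, with SNAI2 between 5.22 and 6.22 for DHT. Of the 69 genes named as called with DHT, 55 passed without vector vehicle replicate 1, 3 with no filter and 6 with the replicate block. The androgen-raised, mitosis, histone and secretory lists passed camera for DHT in each setting with a preset correlation. An estimated correlation was used only in the main fit and in that without vector vehicle replicate 1. No list passed with it in either fit, and it had little power there. Centring and quantile normalization changed no direction among the named genes. Signals near the floor limit the dim genes, since 3.42% to 5.28% of probe sets lay below an intensity of 1. The causes of these differences were not tested, except that fewer arrays or more genes tested are part of the alternatives themselves.

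At an unadjusted p under 0.05 with a change of at least 1.5-fold, BAF57 against vector gave 1447 higher and 433 lower genes, with SMARCE1 (1.16) past that threshold, DHT gave 2440 and 1165, and BAF57 against DHT 326 and 469. Quantile normalization left 646 rises and 141 falls with DHT and 4 genes lower with BAF57 than with DHT. Centring left 659 and 101 with DHT, a share of rises within 10 percentage points of that without it. With no filter 4 genes rose and 0 fell with DHT, 1 was lower with BAF57 than with DHT, and the effects correlated at r = 0.758. With the filter at the 50th percentile 1049 rose and 150 fell with DHT. With trend and robust settings 1335 rose and 199 fell, and 12 were lower with BAF57 than with DHT. With a pseudocount of 16 these counts were 1626, 251 and 15. With only the 4 arrays compared 2 genes rose and 0 fell with DHT, and 34 were higher and 127 lower with BAF57 than with DHT. Array weights gave 8 and 46 in that comparison and 1067 and 97 for DHT. The number of lists past camera with an estimated correlation was 0 for BAF57, 0 for DHT and 0 for BAF57 against DHT, and past fry it was 0, 1 and 2.

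The replicate numbers did not clearly pair the arrays, and a shared effect of the replicate stays open. Vector vehicle had no replicate 2, and the genes that rose with DHT were mostly higher in replicate 3 in every group. Deviations of arrays numbered 3 from their group means correlated across genes at 0.11 for vector with BAF57, 0.27 for vector with DHT and -0.14 for BAF57 with DHT. With the replicate number as a block 11 genes rose and 0 fell with DHT, 0 passed for BAF57 against vector, 10 were lower with BAF57 than with DHT, and 4 lists passed for DHT. In that fit SLC7A5 (-0.30), SLC45A3 (0.23), UCHL1 (-0.53), CCL2 (0.15) and IL1B (0.021) turned sign for BAF57 against vector and UCHL1 (-0.51) for DHT, none of them called in either fit. The crossed pairing of BAF57 and DHT arrays, chosen after the data were seen, called 165 genes higher and 374 lower.

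With each array left out in turn, the lone array of its group being assumed to vary like the others, BAF57 against vector gave 0 to 2045 genes higher and 0 to 657 lower, DHT 1 to 2667 rises and 0 to 1173 falls, and BAF57 against DHT 0 to 34 higher and 0 to 127 lower. SMARCE1 lay between 1.12 and 1.20 and passed without vector vehicle replicate 3. The effects correlated at 0.738 to 0.919 with a covariance of 0.241 to 0.968. From 2 to 8 lists passed for BAF57, 6 to 10 for DHT and 6 to 9 for BAF57 against DHT. Values that turned sign ranged, for BAF57 against vector, from -0.32 to 5.74 for SLC7A5, -2.60 to 0.39 for SLC45A3, -0.36 to 4.96 for UCHL1, -2.14 to 0.12 for CCL2, -1.02 to 0.18 for CLDN5 and -0.025 to 2.56 for THBS1, and for DHT from -0.34 to 4.98 for UCHL1, -0.85 to 0.085 for DST and -0.11 to 0.70 for KLK3.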

Other observations

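All tests in this part were chosen after the results were seen. Small nucleolar RNA genes, many of which guide the modification of ribosomal RNA, fell more often with DHT than other genes did. Of 84 tested, 14 fell (16.7%), against 0.547% of the other genes, and 1 rose (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 7.07e-16 for the falls and 0.0873 for the rises, over 4 tests). Their median log2 change was -0.77, and SNORD38A and SNORD116-6 were among the falls. Without vector vehicle replicate 1, 14 fell too (16.7% against 0.913% of the others, median -0.75). Small nucleolar RNA genes also differed between arrays of one treatment, with a median of -0.35 for BAF57 replicate 3 minus 2, -0.18 for vector replicate 3 minus 1 and 0.0077 for DHT replicate 3 minus 2. Of 344 genes with symbols starting with ZNF, mostly zinc finger genes, 39 rose (11.3%) against 6.15% of the others and 0 fell (Fisher's exact test, adjusted p = 0.000813 and 0.176). The median DHT change of the ZNF genes was 0.11, and 0.22 without vector vehicle replicate 1. Genes of a class are not independent of each other, which these p-values leave out of account.

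Genes on which both BAF57 arrays stood outside the other 4 were no more frequent than chance ordering gives. There were 568 above and 525 below, against 859.467 expected in each direction. That expectation takes the arrays as alike apart from chance, while vector vehicle replicate 1 stood apart and DHT changed many genes. The counts therefore cannot tell whether BAF57 had an effect of its own. Above were IKZF4, an Ikaros family transcription factor gene, at 5.25 and 5.27 against 4.01 to 4.37 elsewhere, LTN1, a ubiquitin ligase gene of ribosome quality control, at 5.37 and 6.25 against 3.18 to 4.58, and SMARCE1. Below were KLK4, a prostate kallikrein gene, at 7.68 and 7.69 against 8.34 to 8.95, the lysosomal gene CLN3 at 3.73 and 4.03 against 4.69 to 5.20 and the kinase gene SRC at 4.20 and 3.57 against 4.83 to 5.22. None of them passed with limma in the BAF57 against vector comparison.

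Single genes far apart on vector vehicle replicate 1, picked after their values were seen, went both ways and were not tested as groups. Above all other arrays were ID1 at 7.90 against at most 4.64 elsewhere, BAMBI at 10.12 against 7.87 and the interferon-induced gene IFI6 at 11.02 against 8.44. Below were BMPER, a BMP-binding protein gene, at 2.25 against at least 5.48, the interferon-stimulated gene PARP14 at 2.61 against 6.33, the growth factor gene IGF1 at 2.76 against 8.20 and the complement regulator gene CD55 at 2.55 against 7.82.

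The distance of this array from the other 5 was weighed against 3 explanations, all technical or of handling, and no biological explanation was tested. Loss of signal from poor RNA or hybridisation as the whole cause would, without rescaling of the arrays, leave genes low only. On this array 28 genes stood more than 2 log2 units above all other arrays at a level over 7, which argues against it as the whole cause. The normalization is not known, and 227 genes lay that far below the others against 31 above, so a partial loss stays open. Androgen exposure as strong as on the DHT arrays was argued against by the 60 androgen-raised genes, whose median difference between replicates 1 and 3 was -0.11 (bootstrap SE 0.155, 28 higher in replicate 1), while the DHT arrays lay 1.34 above replicate 3 (SE of the gap 0.215), and a weaker exposure stays open. RNA of another culture, subline or condition than its partner stays open: 258 genes stood more than 2 log2 units outside the other arrays, in both directions, against at most 1 on any other array. What that RNA may be was not tested here.

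Genes that rose with DHT also lay higher with BAF57 (98.3%). Simulated unchanged groups with a shared simulated vector group gave such a share too (98.4%). For the relation of the effects 3 explanations were weighed. Deviations of single vector arrays as the whole cause are argued against by the covariance across all genes. It was 0.249 and 0.312 when each effect was measured against a different vector array. A deviation common to both vector arrays would remain in this covariance, so that part of the shared vector arrays stays open. A factor that varies between arrays of one treatment, such as RNA or cDNA quality or the state of the culture, stays open, since 93.2% of the 811 genes were higher in BAF57 replicate 3 than in 2, against 54.6% of all genes, with 89.0% against 59.6% for vector and 73.4% against 51.9% for DHT, groups whose arrays also chose these genes. More cycling cells, the biological explanation tested, stay open. The 40 replication-dependent histone genes had a median BAF57 difference of -0.17 (bootstrap SE 0.122, 22 lower). Without vector vehicle replicate 1 it was -0.40 (SE 0.0643, 36 lower), which rests on 1 vector array. With DHT the histone median was -0.68 while the mitosis median was 1.54. The 2 lists thus moved apart there, and the histone level cannot decide. A response to BAF57 that overlaps the androgen response in part stays a hypothesis, as the 60 androgen-raised genes had a median BAF57 difference of 0.08 (camera adjusted p = 0.473) and lay 1.15 lower with BAF57 than with DHT, which goes against one as strong as that to DHT.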
